A study of Mus musculus with 3 samples.

How the data were processed

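Immune cells were measured by droplet single-cell RNA sequencing (10x Genomics Chromium) in 3 mouse libraries, 1 per group. Per the labels' protocols, tumor or matching normal tissue was digested with papain and CD45-positive cells were enriched with a positive selection kit. Reads were mapped to mm10 and counted with Cell Ranger 3.0.2, per the labels' protocols, and Seurat 4 is named in the submitters' processing notes. The limits used to keep cells are not given in the sources used here. In the table, cells have from 501 UMIs upward, at least 201 genes and under 10% mitochondrial UMIs (highest 9.97%).

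The data were a single table of 12668 cells with 64 columns, 49 of which were read and 15 not used. Per the file headers, the authors deposited a count of UMIs and a count of detected genes for each cell, neither normalized. The percent of UMIs from mitochondrial and from ribosomal genes was deposited by the authors, per the file headers, and the gene patterns behind them are not stated. The S and G2M score per cell were deposited by the authors, per the file headers, with gene lists not stated. Library, cluster at 22 resolutions, phase, doublet call and several parallel cell names were deposited as well. No value per gene was analysed here, so that the planned summary of gene expression per class, the planned markers and their low-count alternative could not be run, and class names could not be checked against marker genes.

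Each cell was assigned to a group through its library name. The library labelled HGG carries a title that speaks of no tumor, while its library name and its description say HGG. The HGG group rests on the latter. Nothing in the labels says how many animals went into a library.

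The design, the call rule, the naming rule and the alternatives other than 6 annotation choices and the strata of depth were set before the data were examined. The naming rule took every class with at least 20 cells in 1 or more libraries, which gave 14 of 15. The column used for the classes was picked after the table was seen, among several annotation columns, since the design said only that the authors' annotation would be used. The 4 broad groups (microglia, macrophages and monocytes, T and NK cells, B cells) were defined after the table was seen too. So were the comparisons with 4 other annotation columns, with an earlier merged label for CD8 and CD4 T cells and with the cluster alone, the strict count of T and NK cells and the look at other label sets. In the SingleR and VHove columns, dendritic cells were counted with macrophages and monocytes. Innate lymphoid cells of the first SingleR column were counted with T and NK cells. The class was found to be that of the cluster at resolution 1.5 for all 11607 cells outside activated microglia, CD8, CD4 and NK cells. This clustering was found by scanning all 22, and the next closest left 117 cells off. The 1061 cells of those 4 classes carry the name of an earlier annotation, whose own header calls it final. The word earlier, for this annotation and for the merged label, is only a name used here. The headers do not give the order in which the annotations were made.

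The share of each class was computed over all cells, over myeloid cells (8 classes), over lymphoid cells (5 classes), over cells other than microglia, and over macrophages and monocytes (5 classes). Shares have exact Clopper-Pearson intervals and ratios of shares have Katz log intervals, both at 95%. With 1 library per group no test across groups exists, and no p-value was computed. A class was called higher or lower where the ratio was at least 1.5, or at most its inverse, and the exact intervals did not overlap. A share of 0 was given the limit of 3 counts, and a fold against it is a lower bound from the same 3 counts over the library. The other share enters at its observed value, so that such a bound leaves out the counting error of that share. The limit was 0.0847% in the no-tumor library, 0.0597% in LGG and 0.0732% in HGG. Cells of a library are not independent animals, so that intervals and limits cover counting error only.

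The calculation was tested on simulated counts, with 400 draws for each class at the observed library sizes. For LGG against no tumor, an unchanged class was called higher in 0.0938% of draws on average over 8 classes. A 2-fold change was called in 87.0% and a 3-fold change in 99.8%, each over 7 classes. For HGG against LGG, a 2-fold change was called in 88.5% over 13 classes, and for HGG against no tumor in 84.6% over 7 classes. A 1.5-fold change, at the limit of the call, was called in 34.4% for LGG against no tumor, 40.1% for HGG against LGG and 31.0% for HGG against no tumor. All simulated changes were increases, so that these rates do not cover classes with a lower share. These simulations hold no variation between animals.

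UMIs per cell could not be thinned to a common number without values per gene. A common range of depth, from the highest of the 10th percentiles of the 3 libraries (2985.2 UMIs) to the lowest of their 90th percentiles (14346.3 UMIs), took its place and left 2834 no-tumor, 3160 LGG and 1643 HGG cells. Added after the data were seen, a Mantel-Haenszel ratio of HGG to LGG was computed for glioma associated macrophages over 10 strata of about equal cell number by UMIs, with a Greenland-Robins interval at 95%. Other alternatives were a minimum of 1000 UMIs or of 500 genes, a maximum of 5% mitochondrial UMIs, and leaving out doublet calls with erythrocytes and platelets. Microglia and the top 5% of cells by UMIs were also left out in turn. The majority class of the 53 finest clusters, a centred log-ratio with 0.5 added to each count, a ratio limit of 2, and means in place of medians completed the list. Doublet calls were left in the main analysis. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and plots Matplotlib 3.10.9.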

Results

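Single-cell RNA profiles of CD45-selected immune cells from the right hemisphere of the mouse brain were compared between animals with no tumor, animals labelled LGG (low grade glioma) and animals labelled HGG. Each group was 1 library, so 3 libraries and 12668 annotated cells entered: 3544 with no tumor, 5024 from LGG and 4100 from HGG. The title of the last library speaks of no tumor, whereas its library name and its description say HGG, and it is therefore called the library labelled HGG, or the HGG library for short. The labelled age ran with the group, from 0 to 2 weeks without tumor, 3 to 4 weeks in LGG and 6 to 8 weeks in HGG. The labels do not say whether these weeks run from birth or from the injection of cells that the protocol mentions, and labelled age is used in that open sense. Labelled age, library and tumor group cannot be told apart, and no comparison has a replicate check. All intervals are 95% intervals that cover counting error only, exact (Clopper-Pearson) for a share and Katz log for a ratio of shares. A class is called higher or lower where the ratio reached 1.5 in either direction and the 2 exact intervals lay apart.

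Summed over the cells, the libraries held 32685080 UMIs with no tumor, 61554429 in LGG and 61872213 in HGG. The median cell carried 8826.5, 9863.5 and 12907.5 UMIs in that order, with 2834, 2645.5 and 3097 genes. The mitochondrial share of UMIs had medians of 2.33%, 3.32% and 4.13%. The depositors' annotation names 15 classes, 14 of which reached 20 cells in at least 1 library. Platelets did not, with 16 cells in the no-tumor library, 3 in LGG and 2 in HGG.

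**Figure D1:**
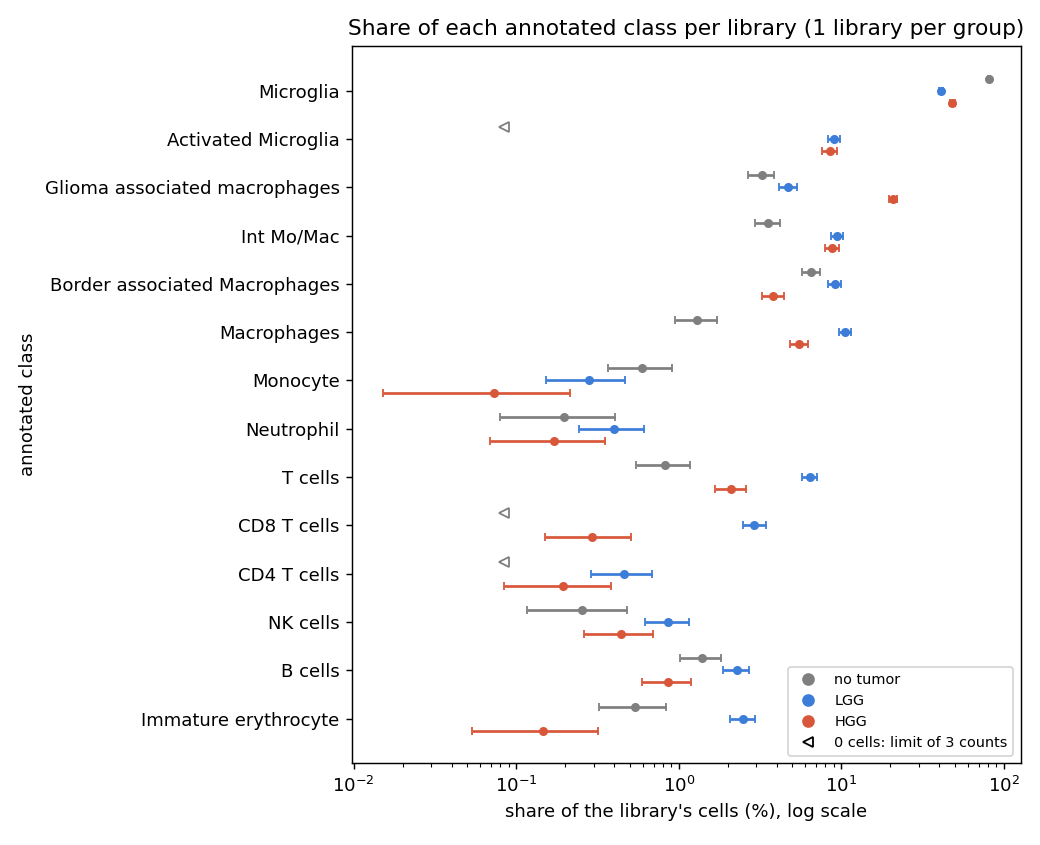
Share of each library's cells in each annotated class, in percent on a log axis, for the no-tumor (grey), LGG (blue) and HGG (red) libraries; bars are exact 95% intervals and open triangles mark the limit that a count of 0 allows. Microglia fill 81.2% of the no-tumor library, and glioma associated macrophages reach 20.8% in HGG.

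The first comparison asks how the immune compartment of the LGG library differed from that of the brain without tumor. Microglia, the resident macrophages of brain tissue, made up 81.2% of the no-tumor cells (79.9 to 82.5%) and 41.0% of the LGG cells (39.7 to 42.4%), a ratio of 0.506 (0.487 to 0.525). The no-tumor class includes 186 cells of clusters whose tumor-library cells are all named activated microglia. Both microglia classes together stood at 50.1% in LGG against 81.2%, a ratio of 0.617 (0.597 to 0.637). The lower share met the call rule over all cells, but not within the range of depth common to the 3 libraries (0.716, 0.694 to 0.738), nor among myeloid cells (0.704, 0.684 to 0.725), nor with 4 other deposited annotations, where the ratio was 0.677 to 0.815. The class called macrophages was 8.11 times as large a share in LGG (6.02 to 10.9), at 10.5% against 1.298%. This holds for the class as named, since other deposited labels called most of its 801 cells over all libraries microglia. The counts were 798 with the first SingleR label, 771 with the second, 656 with the second VHove label and 592 with the earlier merged label. The class named Int Mo/Mac, an abbreviation the labels do not spell out, stood at 9.43% against 3.53%, a ratio of 2.67 (2.21 to 3.24). T cells without a finer name were at 6.39% against 0.818%, a ratio of 7.81 (5.35 to 11.4). In all, 9 of the 14 classes as named were higher and 1 was lower in LGG.

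Among lymphocytes, CD8 T cells, the cytotoxic lineage, held 147 LGG cells (2.93%) and 0 of the 3544 no-tumor cells, which allows a share of up to 0.0847% for the class as named. By that name the share was at least 34.6-fold higher, and at least 13.0-fold higher with microglia left out of the denominator. CD4 T cells, the helper lineage, held 23 LGG cells (0.458%) and again 0 without tumor, at least 5.41-fold higher by name and at least 2.04-fold with microglia left out. These bounds hold for the names only and take the LGG share as exact. For CD4 T cells with microglia left out, the exact interval starts at 0.582% in LGG and ends at 0.552% without tumor. An earlier deposited label, compared after the data were seen, gave CD8 to 265 LGG and 9 no-tumor cells, a ratio of 20.8 (10.7 to 40.3), which is below the bound by name. Over all libraries, its CD8 name covers 135 of the 159 cells of the CD8 class. It also covers 90 unspecified T cells, 40 NK cells, 27 cells of the Int Mo/Mac class and 10 B cells, so that it is not a recheck of the class alone. Giving each finest cluster its majority class put 119 LGG and 2 no-tumor cells in the CD8 class, a ratio of 42.0 (10.4 to 169.7). The earlier label gave CD4 to 58 and 2 cells, a ratio of 20.5 (4.9997 to 83.7). Its CD4 name covers mostly other cells than the CD4 class. Of the 31 cells of that class, it called 6 CD4 and 21 regulatory T cells. NK cells were at 0.856% against 0.254% (ratio 3.37, 1.65 to 6.90) and B cells at 2.27% against 1.38% (ratio 1.64, 1.18 to 2.29). Immature erythrocytes, precursors of red blood cells, were at 2.49% against 0.536% (ratio 4.64, 2.87 to 7.51), a ratio that was 8.68 (4.41 to 17.1) with at least 1000 UMIs per cell and 4.48 (1.74 to 11.5), from 31 and 5 cells, with at least 500 genes. Cells of this class carried a median of 898 UMIs without tumor and 14053 in LGG. The minimum of 1000 UMIs thus kept 9 of the 19 no-tumor and 110 of the 125 LGG cells, which raises the ratio. Their LGG cells carried a median of 302 genes, and other deposited labels disagreed on the class. Of all 150 cells, the first SingleR label called 108 microglia, the second called 79 erythrocytes and 55 microglia, and the earlier label called 54 erythrocytes and 24 microglia. Within lymphoid cells, the 3 T cell classes together were at 75.8% against 33.3% and B cells were at 17.6% against 56.3%. In that denominator B cells were lower in LGG (ratio 0.312, 0.244 to 0.401), and unspecified T cells (1.49, 1.09 to 2.02), NK cells (0.641, 0.324 to 1.27) and CD4 T cells met no call. With the first SingleR label the call for B cells over all cells ended (1.61, 0.925 to 2.79), and with the second the ratio was 2.76 (1.73 to 4.40). Of the 198 cells called B cells, 81 were called microglia by the first SingleR label, 50 by the second, 34 by the second VHove label and 0 by the earlier label, and from 73 to 111 were called B cells by these 4. Of the 436 unspecified T cells, the same labels called 265, 203, 143 and 1 microglia, the earlier label placing 163 in a macrophage cluster instead, and the scANVI label called 245 T cells.

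Activated microglia, 453 LGG cells (9.02%, 8.24 to 9.84%) and 0 no-tumor cells, were named by library as well as by cluster. Every one of the 801 cells of this class came from 2 clusters of the clustering at resolution 0.4, and every tumor-library cell of those clusters carries the name. The same clusters hold 200 no-tumor cells, of which 186 are named microglia, 10 monocytes and 4 glioma associated macrophages. Other labels differed on the identity. The fifth version of a marker-list label (SCSA) called all 1001 cells of these clusters granulocytic MDSC, in its own words. The eighth version gave the name Ccl3 expressing myeloid to 453 LGG, 348 HGG and 0 no-tumor cells. Of the 801 cells of the class, the first SingleR label called 778 microglia and the second 754. By cluster rather than by name, the shares were 5.64% without tumor (4.91 to 6.45%), 9.02% in LGG and 8.49% in HGG. The ratio to the no-tumor library was then 1.60 in LGG (1.36 to 1.88) and 1.504 in HGG (1.27 to 1.78). By name, the share was at least 106.5-fold higher in LGG, with 0 of those 200 no-tumor cells carrying the name. Giving each finest cluster its majority class put 120 no-tumor, 258 LGG and 167 HGG cells in activated microglia, with ratios to no tumor of 1.52 in LGG (1.23 to 1.88, called higher) and 1.203 in HGG (0.956 to 1.51, no call), and left 0 cells in the CD4 class.

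Classes without a call included glioma associated macrophages, at 4.74% in LGG and 3.24% without tumor (ratio 1.46, 1.17 to 1.82), and border associated macrophages, the macrophages of meninges, vessels and choroid plexus, at 9.12% and 6.52% (ratio 1.399, 1.201 to 1.63). Neutrophils were at 0.398% and 0.198%, and monocytes at 0.279% and 0.593%, both with overlapping intervals. Within the common range of depth, 2985.2 to 14346.3 UMIs, the call for B cells ended (1.92, 1.16 to 3.17), and glioma associated macrophages (1.62, 1.22 to 2.15) and border associated macrophages (1.56, 1.26 to 1.94) were called higher. The Int Mo/Mac class was still called, with its ratio down to 1.603 (1.23 to 2.10), while that of unspecified T cells was 13.5 (6.59 to 27.5), that of NK cells 5.08 (2.14 to 12.1) and that of immature erythrocytes 43.0 (5.95 to 311.7), from 48 cells against 1. Glioma associated macrophages also met the call with at least 500 genes per cell, without doublet calls, without the top 5% of cells by UMIs and with the cluster alone, at 1.504 to 1.68. With at most 5% mitochondrial UMIs, border associated macrophages were called higher (1.76, 1.48 to 2.10) and B cells were not called (1.52, 1.02 to 2.28), nor were B cells without doublet calls (1.58, 1.11 to 2.26). Without the top 5% of cells, unspecified T cells were at 12.5 (7.45 to 21.0). Among myeloid cells these 2 classes were called higher too, at 1.67 (1.34 to 2.07) and 1.597 (1.37 to 1.86). With microglia left out of the denominator, border associated macrophages were lower in LGG (ratio 0.527, 0.461 to 0.602), as were glioma associated macrophages (0.550, 0.448 to 0.676), B cells (0.618, 0.447 to 0.855) and monocytes (0.177, 0.0906 to 0.347), while the Int Mo/Mac class (1.01, 0.844 to 1.204), NK cells (1.27, 0.622 to 2.59) and immature erythrocytes (1.75, 1.09 to 2.81) met no call. The macrophage class (3.06, 2.29 to 4.08) and unspecified T cells (2.94, 2.03 to 4.26) were still higher. Relative to the mean of all log counts, the Int Mo/Mac class (0.631), NK cells (0.764) and B cells (0.733) turned below 1. For the Int Mo/Mac class and NK cells, that mean includes activated microglia, CD8 and CD4 T cells, at 0 without tumor before 0.5 was added. Those zeros lower the ratio of every other class in LGG, so that neither value decides a direction.

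**Figure D2:**
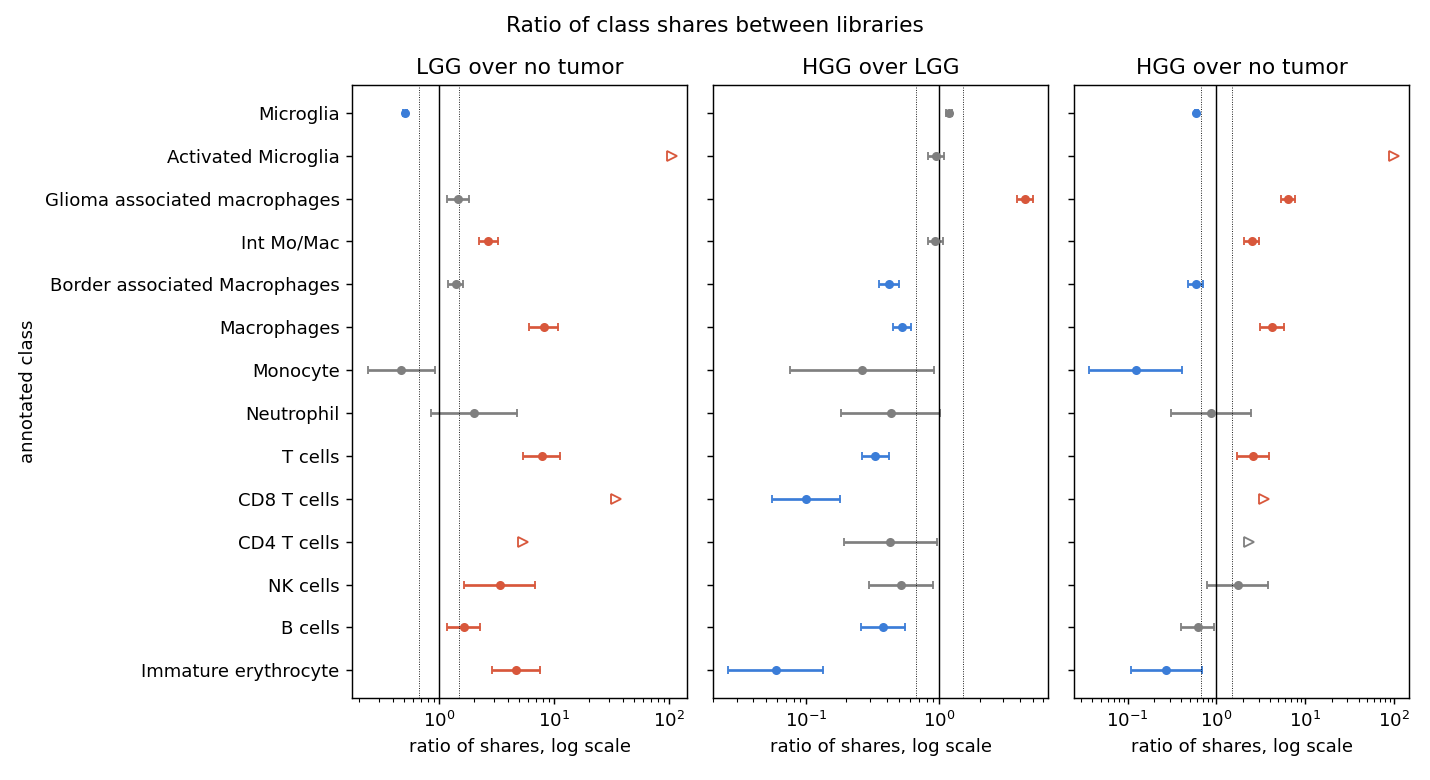
Ratio of class shares for each pair of libraries on log axes with 95% Katz intervals; red marks classes called higher, blue lower and grey neither, dotted lines stand at the ratio of 1.5 and its inverse, and open triangles are lower bounds against a count of 0, for the classes as named. Between HGG and LGG, only glioma associated macrophages lie to the right of the upper line, at 4.40.

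The second comparison sets the library labelled HGG, despite its title, against LGG. Glioma associated macrophages made up 20.8% of the HGG library (19.6 to 22.1%) and 4.74% of the LGG library (4.17 to 5.36%), a ratio of 4.40 (3.83 to 5.05), and were the only class of the 14 called higher. Among macrophages and monocytes alone they were 53.4% in HGG and 13.9% in LGG. The cells of this class were also deeper, with a median of 25204.5 UMIs in HGG and 10216 in LGG. Among cells within the common range of depth, the ratio was 1.70 (1.33 to 2.17). The filter to that range kept 115 of the 854 HGG cells of the class (13.5%) and 130 of the 238 LGG cells (54.6%), so that this ratio rests on the shallower part of the class. Over 10 strata of UMIs that keep all cells, a comparison added after the data were seen, the Mantel-Haenszel ratio was 3.58 (3.06 to 4.18), with single strata from 0.928 to 21.0 and the highest ratios in the 2 deepest. Other labels disagreed on what these cells are. Of the 1207 cells of the class, the first SingleR label called 1184 microglia, the second called 953 microglia and 249 macrophages, and the earlier label called 796 macrophages, a further 70 M1 macrophages and 274 microglia. Of the 801 cells of the macrophage class, the first SingleR label called 798 microglia, and the earlier label called 592 microglia and 187 macrophages. In another deposited layer of names, 284 of the 1207 are microglia, 199 of them in HGG.

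Lower in HGG than in LGG were 6 classes. Border associated macrophages were at 3.80% against 9.12% (ratio 0.417, 0.350 to 0.498) and the macrophage class at 5.51% against 10.5% (ratio 0.524, 0.450 to 0.608). Unspecified T cells were at 2.10% in HGG (ratio 0.328, 0.260 to 0.415), CD8 T cells at 0.293% (ratio 0.10, 0.0556 to 0.180) and B cells at 0.854% (ratio 0.376, 0.258 to 0.548). Immature erythrocytes were at 0.146%, or 6 cells (ratio 0.0588, 0.0260 to 0.133). Microglia (48.3% and 41.0%), activated microglia (8.49% and 9.02%) and the Int Mo/Mac class (8.78% and 9.43%) differed by less than the ratio asked for. CD4 T cells (8 and 23 cells), NK cells (18 and 43) and neutrophils (7 and 20) had overlapping intervals. Under the CD4 name of the earlier label, which covers mostly other cells than the class, the share was called lower, at 12 HGG and 58 LGG cells (0.254, 0.136 to 0.471). Without the top 5% of cells monocytes were called lower (0.0942, 0.0123 to 0.720). Without doublet calls monocytes were also called lower, with 0 HGG cells against 10 in LGG, at least 2.81-fold. Within the common range of depth, the calls for border associated macrophages (0.890, 0.708 to 1.12) and B cells (0.9003, 0.545 to 1.49) ended, and the Int Mo/Mac class was called higher in HGG (1.52, 1.196 to 1.93). Unspecified T cells (0.497, 0.336 to 0.734) and CD8 T cells (0.194, 0.0982 to 0.385) were still lower there, as were CD8 T cells with the majority class of the finest clusters (0.216, 0.136 to 0.343) and immature erythrocytes with at least 500 genes per cell (0.118, 0.0360 to 0.384). Among lymphoid cells, CD8 T cells were lower (0.333, 0.190 to 0.584), while unspecified T cells (1.09, 0.928 to 1.29) and B cells (1.25, 0.894 to 1.75) turned above 1 without a call. The call for B cells also ended with the first SingleR label (0.508, 0.289 to 0.893). Relative to the mean of all log counts the macrophage class was at 1.07.

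Taken as broad groups, macrophages and monocytes met no call between both tumor libraries, at 39.0% in HGG (37.5 to 40.5%) and 34.1% in LGG (32.8 to 35.4%), a ratio of 1.14 (1.08 to 1.21). With the first SingleR label the direction turned and the group was called lower in HGG, at 9.24% (8.37 to 10.2%) against 17.4% (16.4 to 18.5%), a ratio of 0.531 (0.474 to 0.594). That group included dendritic cells, 38 of 379 cells in HGG and 127 of 875 in LGG. Of these, 34 in HGG and 107 in LGG lay in the Int Mo/Mac class, which the main group counts too. The same label called 1184 of the 1207 glioma associated macrophages microglia, and 798 of the 801 cells of the macrophage class. Those cells are in the main group but not in the group by this label. The second SingleR label (0.964) and the second VHove label (0.906) also turned the direction, without a call. Both counted dendritic cells too, with the VHove label 353 of 1054 HGG and 368 of 1425 LGG cells of the group. T and NK cells were at 3.02% and 10.6%, a ratio of 0.285 (0.235 to 0.344), and of 0.473 (0.363 to 0.618) within the common range of depth. Counting T and NK cells more strictly, without doublet calls and with a T, NKT, NK or innate lymphoid name from the first SingleR label, left 56 HGG, 247 LGG and 12 no-tumor cells. The ratio of HGG to LGG was then 0.278 (0.208 to 0.370).

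The third comparison sets the library labelled HGG against the brain without tumor, and its directions rest on that label as well. Microglia were at 48.3% against 81.2%, a ratio of 0.595 (0.574 to 0.616). Both microglia classes together, at 56.8% against 81.2%, had a ratio of 0.699 (0.678 to 0.721) and met no call. Higher in HGG were glioma associated macrophages (ratio 6.42, 5.31 to 7.76), the macrophage class (5.51% against 1.298%, ratio 4.25, 3.10 to 5.81), the Int Mo/Mac class (8.78% against 3.53%, ratio 2.49, 2.04 to 3.04) and unspecified T cells (2.10% against 0.818%, ratio 2.56, 1.69 to 3.90). CD8 T cells, 12 against 0, were at least 3.46-fold higher by name. That bound takes the HGG share as exact, whose exact interval starts at 0.151%, while that of the no-tumor share ends at 0.104%. The earlier label, whose CD8 name also covers cells of other classes, gave 32 HGG cells against 9, a ratio of 3.07 (1.47 to 6.43), below that bound. The majority class of the finest clusters gave 21 against 2, a ratio of 9.08 (2.13 to 38.7). With activated microglia by name, 6 classes were higher.

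Besides microglia, 3 classes were lower in HGG than without tumor. Border associated macrophages were at 3.80% against 6.52% (ratio 0.584, 0.479 to 0.712). Immature erythrocytes were at 0.146% against 0.536% (ratio 0.273, 0.109 to 0.683). The class named monocyte counted 3 cells against 21 (ratio 0.123, 0.0369 to 0.414). All 3 HGG cells carried a doublet call and 0 of the 21 did, so that without doublet calls the class was at 0 in HGG, at least 8.13-fold lower. Of its 38 cells over all libraries, 27 were called endothelial, fibroblast or stromal by the first SingleR label. Taking each cell's class from its cluster at resolution 1.5 alone, the monocyte ratio was 0.617 (0.319 to 1.196) and that of microglia 0.687 (0.666 to 0.709), both without a call. With the majority class of the finest clusters they were 0.659 (0.344 to 1.26) and 0.680 (0.657 to 0.704), again without a call. Immature erythrocytes met no call with at least 1000 UMIs per cell (0.390, 0.120 to 1.27), with at least 500 genes (0.527, 0.126 to 2.20), with at most 5% mitochondrial UMIs (0.318, 0.118 to 0.856) or without the top 5% of cells (0.399, 0.152 to 1.05). Border associated macrophages met none with at most 5% mitochondrial UMIs (0.849, 0.678 to 1.06). B cells (0.854% and 1.38%), NK cells (0.439% and 0.254%), neutrophils (0.171% and 0.198%) and CD4 T cells (8 and 0) met no call. CD4 T cells by name were called higher within the common range of depth (7 against 0, at least 4.02-fold) and with at most 5% mitochondrial UMIs (8 against 0, at least 3.06-fold). Within the common range of depth 0 classes were called lower, microglia standing at 0.692 (0.664 to 0.722) and border associated macrophages at 1.39 (1.08 to 1.80), glioma associated macrophages were at 2.76 (2.07 to 3.68), unspecified T cells were at 6.68 (3.08 to 14.5), and NK cells were called higher (4.89, 1.93 to 12.4). With microglia left out of the denominator, glioma associated macrophages (2.79, 2.35 to 3.32) and the macrophage class (1.85, 1.36 to 2.51) were still higher, while unspecified T cells (1.12, 0.739 to 1.68), the Int Mo/Mac class (1.08, 0.902 to 1.301) and CD8 T cells by name (at least 1.505) met no call. Border associated macrophages (0.254, 0.212 to 0.305) and B cells (0.269, 0.176 to 0.411) were then lower. Among lymphoid cells B cells were lower too (0.391, 0.276 to 0.553), unspecified T cells were still higher (1.62, 1.17 to 2.26) and CD8 T cells met no call. Without the top 5% of cells, unspecified T cells were at 4.55 (2.63 to 7.89).

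**Figure D3:**
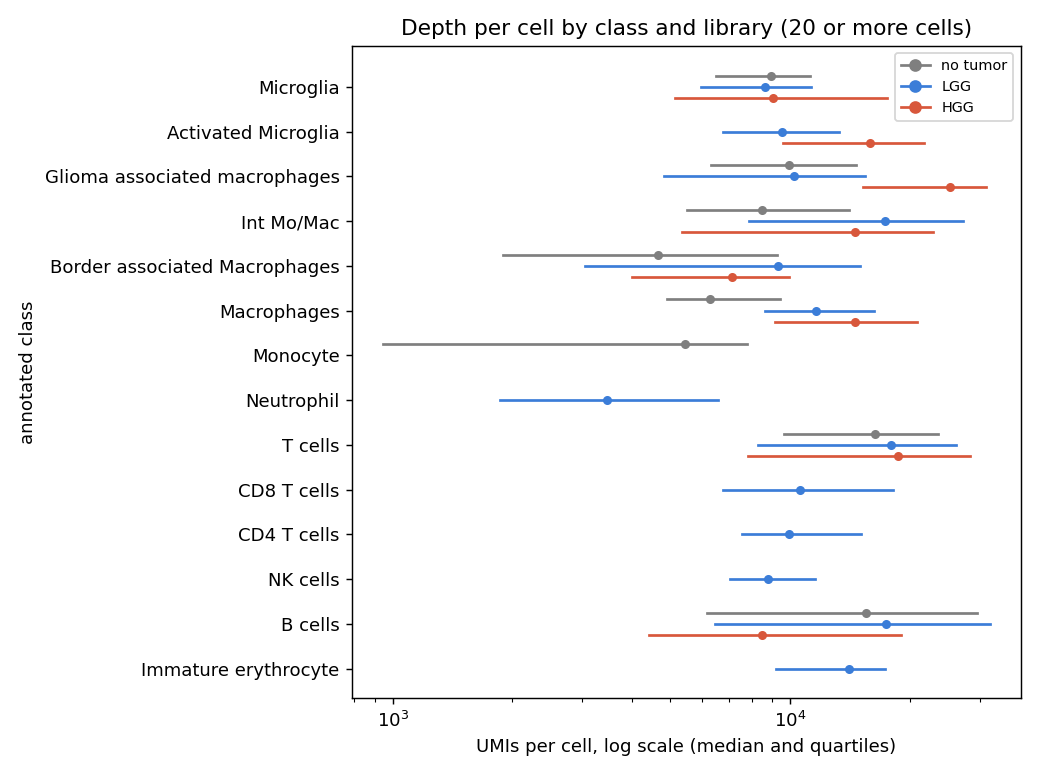
UMIs per cell on a log axis for each class and library with at least 20 cells; points are medians and lines run between the quartiles. Glioma associated macrophages reach a median of 25204.5 UMIs in HGG, against 10216 in LGG and 9947 without tumor.

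Depth differed between classes as well as libraries. Microglia had similar medians in the no-tumor (8967), LGG (8646.5) and HGG (9072) libraries, but a wider spread in HGG. Their upper quartiles were 11230, 11321 and 17570.5 UMIs in that order, and their lower quartiles 6515, 5966.5 and 5143.5. The Int Mo/Mac class had 8476, 17331.5 and 14592.5 UMIs, and border associated macrophages 4655, 9328 and 7163.5. Unspecified T cells had high medians throughout, 16323, 17984 and 18743. The deposited doublet calls, which had not been removed from the table, covered 439 of the 12668 cells (3.47%, 3.15 to 3.80%). They covered 20.0% of the unspecified T cells (16.3 to 24.0%), 13.6% of B cells, 12.2% of the Int Mo/Mac class and 1.24% of microglia.

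The deposited cell cycle phase was G2M for 6.86% of the no-tumor cells (6.05 to 7.74%), 14.9% of the LGG cells (13.9 to 15.9%) and 10.7% of the HGG cells (9.78 to 11.7%). S was called in 24.9%, 29.3% and 26.7%. Each call was simply the larger of the 2 phase scores where it exceeded 0. Of the G2M calls, 76.5%, 71.6% and 65.8% had a score under 0.05. These values are for all cells of a library pooled. In the Int Mo/Mac class, G2M was called in 36.8% of no-tumor, 33.1% of LGG and 36.1% of HGG cells, with median scores of 0.498, 0.270 and 0.326 among the called cells, and 28.3%, 35.7% and 22.3% of those calls were under 0.05. Depth differed between the libraries, and cycling was not read from phase calls alone in any class. Free RNA in the droplets, which can enter such scores, was not examined.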

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

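The 3 tests of whether too few no-tumor cells were sampled, the test of glioma associated macrophages over strata of depth, the tests of activated microglia and of CD8 and CD4 T cells taken apart, and the look at other label sets were chosen only after the result was seen.

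Immature erythrocytes moved in opposite directions in the tumor libraries, with a share 4.64 times that of the no-tumor library in LGG and 0.273 times in HGG. The LGG ratio was 8.68 (4.41 to 17.1) with at least 1000 UMIs per cell. With at least 500 genes it was 4.48 (1.74 to 11.5), from 31 cells against 5, and in the common range of depth it was 43.0 (5.95 to 311.7), from 48 cells against 1. Cells of the class had a median of 898 UMIs without tumor and 14053 in LGG, so that the limits on UMIs removed unequal parts of it. With 1 library on each side the difference between these effects was not tested, and the HGG value rests on 6 cells. The lower call in HGG ended with at least 1000 UMIs (4 cells against 9) and with at least 500 genes (3 against 5). It also ended with at most 5% mitochondrial UMIs (5 against 18) and without the top 5% of cells. In the common range of depth the HGG ratio was 3.45, from 2 cells against 1, with an interval from 0.313 to 38.0.

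Other deposited labels name cells for which the 15 classes have no name. The dendritic, regulatory T cell and proliferating TAM labels had shares above those of the no-tumor library. The scANVI labels DC1 to DC4, dendritic cells, took 3.503% of LGG and 1.32% of HGG cells against 0.226% without tumor. The first label set named for VHove gave 3.58% and 1.66% against 0.310%. The latter set also named regulatory T cells in 1.19% of LGG and 0.268% of HGG cells and in 0 of 3544 no-tumor cells, which allows up to 0.0847%. Its proliferating TAM label took 2.45% of LGG and 2.59% of HGG cells against 1.19% without tumor. For the mast cell and plasma B cell labels of both sets, the intervals overlapped between the libraries.

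The absence of 3 classes from the no-tumor library is the first pattern weighed, and the test was written for activated microglia, CD8 and CD4 T cells together. From the LGG rate of these names in each finest cluster, 243.3 no-tumor cells would carry them, against a bound of 10 and 0 found, which is consistent with names given to the tumor libraries only. Taken apart, activated microglia kept that reading (235.0 cells), and the 200 no-tumor cells in the clusters of that class argue against too few cells sampled. The 319.6 no-tumor cells that the LGG share would give decide nothing, because the naming fixes the 0 they are set against. CD8 and CD4 T cells came to 8.27, between the bounds of 3 and 10, which leaves naming and a true scarcity undecided. By the earlier label, which names no-tumor cells too, the LGG share of its CD8 and CD4 names together was 20.7 times as large (11.4 to 37.7). Those names cover partly other cells than the classes and leave out regulatory T cells. The ratio argues against too few cells sampled and leaves naming, scarcity, labelled age and tumor group open.

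The second pattern is the high depth of the unspecified T cell class, where doublet calls are frequent. Cells of the class that the first SingleR label called microglia had doublet calls in 70 of 265 cells, and those it called T, NKT or T gamma-delta in 5 of 98, a ratio of 5.18 (2.15 to 12.4). Median UMIs were 21573 and 7309.5. These values are consistent with T cells captured together with microglia in part of the class. A doublet caller can itself follow depth, which was not tested, and no biological explanation was tested.

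The third pattern is the larger share of glioma associated macrophages in HGG, at 4.40 times that of LGG. Within the common range of depth, which kept 13.5% of the HGG and 54.6% of the LGG cells of the class, the ratio was 1.70 (1.33 to 2.17), with its interval reaching below the bound of 1.5, whereas over 10 strata of depth that keep all cells it was 3.58 (3.06 to 4.18), which argues against depth as the whole cause, although strata ran from 0.928 to 21.0. HGG cells were 70.6% of the finest clusters where the class is the majority, and from 56.1% to 83.7% of each of the 4. These values lie under the bound of 90% set for a name given to a cluster of that library alone. Of the 1207 cells of the class, however, 854 were HGG cells. The pooled percent nearly restates this, had little room to reach the bound and decides nothing about the naming. A cluster mostly of 1 library may still reflect that library, and with 1 library per group its preparation could not be examined. Tumor group and labelled age stay open and were not tested apart.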

How the results depend on the processing

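The 4 broad groups and the numbers of classes called were recomputed under each alternative that allows it (microglia here are both microglia classes), and the comparisons with other annotation columns, with the earlier label for CD8 and CD4 T cells, over strata of depth and with the cluster alone were chosen after seeing the data. Of 225 values, 158 stayed within the interval of the reported ratio or within 1.5 times the reported number, 64 moved out and 3 reversed, meaning that a ratio with a call came to lie on the other side of 1. Ratios without a call crossed 1 in a further 7 of the broad values, counted above as moved or stayed. Of 404 values for single classes and for depth, 298 stayed, 98 moved and 8 reversed. Here a further 21 ratios without a call crossed 1: 10 still met none, 3 gained one and 8 had no call defined. The 404 values are spread unevenly over the alternatives. The minimum of 1000 UMIs gave 69, of which 68 stayed, and the common range of depth gave 32, of which 12 stayed. A minimum of 1000 UMIs or of 500 genes moved none of the broad groups or numbers. The cause of a change was not tested unless named. No paired analysis was possible because each group is 1 library. The alternative for gene values was not run, as no value per gene was analysed here. Classes at 0 have a ratio with the earlier label (CD8 and CD4 T cells) and with the majority class of the finest clusters (activated microglia and CD8 T cells), set against their lower bounds. Activated microglia also have one by their clusters at resolution 0.4, at 1.60 in LGG and 1.504 in HGG against no tumor.

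Leaving microglia out of the denominator, which by construction raises all other shares most where microglia are most frequent, reversed the LGG to no-tumor ratio of macrophages and monocytes (0.846) and of B cells (0.618). Among myeloid cells it reversed glioma associated macrophages (0.651) and border associated macrophages (0.624) in LGG, and the Int Mo/Mac class in HGG (0.977), all against no tumor. T and NK cells moved to 3.74 in LGG and 1.23 in HGG against no tumor, macrophages and monocytes to 1.32 for HGG over LGG and 1.12 for HGG over no tumor, and B cells to 0.269 for HGG over no tumor. Classes higher than without tumor became 4 in LGG and 2 in HGG, and classes lower in LGG became 4.

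In the common range of depth, microglia moved to 0.716 in LGG and 0.782 in HGG against no tumor, and T and NK cells to 16.7 and 7.89. Against no tumor in HGG, macrophages and monocytes were at 2.30 and B cells at 1.72, border associated macrophages reversed to 1.39 and immature erythrocytes to 3.45, and 0 classes were lower. For HGG over LGG, macrophages and monocytes were at 1.005, T and NK cells at 0.473 and B cells at 0.9003, with 2 classes higher. Without the top 5% of cells, T and NK cells were at 14.6 in LGG and 4.60 in HGG and B cells at 0.983 in HGG, against no tumor. Without doublets, erythrocytes and platelets, microglia were at 0.647 for LGG over no tumor and 1.08 for HGG over LGG. Classes lower in HGG than without tumor numbered 2 with at most 5% mitochondrial UMIs, with the majority class of the finest clusters, with the cluster alone and with a ratio limit of 2. The last also left 0 classes lower in LGG.

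Under 4 other annotations many ratios changed size, and microglia were no longer called lower in LGG. Against no tumor in LGG, microglia were at 0.815 with the first SingleR label, 0.751 with the second, 0.677 with the second VHove label and 0.719 with the earlier annotation. Macrophages and monocytes, which include dendritic cells in the first 3, were at 2.70, 2.54, 3.06 and 1.39 in that order, the last without a call. T and NK cells were at 17.8, 17.0 and 15.5 with the first 3, and B cells at 2.76 with the second SingleR label. For HGG over LGG, macrophages and monocytes were at 0.531 (called lower), 0.964, 0.906 and 1.45, T and NK cells at 0.212 with the second SingleR label and 0.202 with the VHove label, and microglia at 1.18 with the VHove label and 0.986 with the earlier annotation. For HGG over no tumor, microglia were at 0.960, 0.860 and 0.8003 with the first 3, macrophages and monocytes at 1.43 with the first SingleR label and 2.02 with the earlier annotation, T and NK cells at 4.18 with the first SingleR label, and B cells at 1.18 with the second SingleR label and 1.03 with the VHove label.

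The centred log-ratio, relative to the mean of all log counts, reversed the Int Mo/Mac class (0.631), NK cells (0.764) and B cells (0.733) for LGG over no tumor, and the macrophage class (1.07) for HGG over LGG. The Int Mo/Mac and NK values draw on a mean that includes activated microglia, CD8 and CD4 T cells, at 0 without tumor before 0.5 was added. Those zeros lower every other class in LGG, so that neither value decides a direction. For broad groups on the log-ratio scale, LGG over no tumor was 0.277 for microglia, 1.01 for macrophages and monocytes and 4.40 for T and NK cells. HGG over LGG was 2.53 for microglia, 2.55 for macrophages and monocytes, 0.638 for T and NK cells and 0.849 for B cells. Counts under 25 cells, as for neutrophils, monocytes and CD4 T cells, limit what differences these libraries show.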

Other observations

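All label sets below were looked at only after the table was seen. Dendritic cells, the antigen-presenting cells that prime T cells, have no class of their own in the annotation used. Of the 238 cells with a scANVI dendritic label, 194 (81.5%) lay in the Int Mo/Mac class, including all 31 labelled DC4. The share of these labels in LGG was 15.5 times that without tumor (7.65 to 31.5) and 0.376 times as large in HGG as in LGG (0.278 to 0.509). The first SingleR label gave 127 LGG, 38 HGG and 2 no-tumor dendritic cells, with a ratio of HGG to LGG of 0.367 (0.256 to 0.526). The second label set named for VHove differed, with conventional dendritic cells at 8.61% in HGG and 7.32% in LGG, a ratio of 1.18 (1.02 to 1.35). Of its 747 such cells, 236 were in the microglia class.

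Regulatory T cells, which restrain other T cells, were named in 60 LGG and 11 HGG cells by the first VHove label set, a ratio of 0.225 (0.118 to 0.427). Of these 71 cells, 26 were in the CD4 class and 22 among unspecified T cells. An earlier merged label named 59 LGG, 13 HGG and 1 no-tumor cell. Cells labelled proliferating TAM met no call between HGG and LGG (ratio 1.06, 0.817 to 1.36), and 196 of the 271 cells were in the Int Mo/Mac class.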
